A study of Mus musculus with 9 samples.

How the data were processed

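RNA was measured in 9 libraries of HT22, an immortalised mouse hippocampal neuronal line. The labels place 3 libraries in an experimental group, 3 in an intervention group and 3 in a control group. The series title names hemin, an oxidised form of heme, and a bioactive micelle called PPP8. The labels do not say which cultures received either one, so the groups keep the names of the labels and no condition was read from the expression values. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

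Per the labels' protocols, RNA was isolated with a Qiagen RNeasy kit and libraries were made with a SMARTer mRNA-Seq kit. Sequencing was on an Illumina NovaSeq, per the series' design text. The authors deposited 1 table of FPKM (fragments scaled to gene length and library size) with 29756 entries, 1 value per entry and library, written with 2 decimals. The submitters' processing notes name the mouse genome build mm10. The aligner, the counting program, the annotation and the use of strand are not given in the sources used here. Genes with near-identical copies, such as Hspa1a and Hspa1b, the ferritins and the ribosomal protein genes with their pseudogenes, are therefore uncertain as single genes, as are genes that overlap another gene.

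The sequencing depth of each library is unknown, because FPKM holds no read number. The low values gave no whole-read steps: of 8158 values above 0 of genes under 200 nt, 1407 (17.2%) were below what 1 read is worth in a library of 200 M reads, which fractions of fragments, deeper libraries or other gene lengths would each give. Whole reads were therefore not recovered and no count test was run, although one had been planned in case counts could be had. FPKM summed to between 316912 and 339943 per library. Precision was taken from the spread between replicates alone.

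Each value was transformed to log2(FPKM + 1). An entry was tested when its FPKM was at least 1 in at least 3 of the 9 libraries, which left 11974 entries. For 118 entries whose symbol occurs more than once, the entry with the highest mean kept the symbol, and 34 such entries were tested. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), with all 9 libraries in 1 fit and no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, 2-sided. Fold changes on the log2(FPKM + 1) scale understate the change of genes with low FPKM, and ratios of mean FPKM are given beside them. Every adjusted p of a gene is from limma.

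The genes named were chosen by a rule. It took, per comparison, up to 10 higher and 10 lower called genes with the largest change, whose groups did not overlap and whose mean FPKM was at least 5 in the higher group, leaving out predicted genes and ribosomal protein genes. It also took 17 genes named in advance whatever they showed, and up to 4 members per gene list with the smallest adjusted p. A few genes outside the rule are named as chosen after their values were seen. Of the 27 gene lists, 23 had at least 5 measured members and were tested with camera, at a preset correlation between genes of 0.01. Only members that passed the filter on FPKM count as measured. Camera with an estimated correlation and fry were alternatives, and list p-values were adjusted over the lists within a comparison. The lists were heme and iron, NRF2 targets, integrated stress response with ATF4 targets, unfolded protein response, heat shock, metallothioneins and metal transport, ferroptosis regulators, p53 and apoptosis, NF-kB and cytokines, interferon response, immediate early genes, autophagy and lysosome, cholesterol synthesis, fatty acids and lipids, hypoxia and glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, DNA replication, mitosis, ribosomal proteins, proteasome, extracellular matrix with TGF-beta targets, and neuronal genes. Markers of astrocytes, of microglia and blood, of oligodendrocytes and endothelium, and RNA-quality transcripts were too few to test as lists. The groups, comparisons, lists, naming rule and alternatives were set before the data were examined. List members without a tested entry were not analysed here.

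The intervention and experimental groups' differences share the experimental libraries. The overlap of their calls was set beside 100 simulations of unchanged groups that share those libraries and beside the overlap of independent lists. Gene lengths, GC content and positions came from GENCODE M21 on mm10, which gave a length and GC content for 98.05% of the tested entries. The scripts were tested on simulated data with 11974 genes. For experimental against control they recovered 23, 45, 49 and 50 of 50 genes changed by 1.25, 1.5, 2 and 4 times, and called 8 unchanged genes. For intervention against experimental the numbers were 16, 39, 47 and 48 of 50, with 7 unchanged genes called. For intervention against control they were 18, 43, 49 and 50 of 50, with 9 unchanged genes called. Each fold change was given to 50 of the 11974 simulated genes, whereas 8856 genes were called in the real comparison of experimental against control. The recovered numbers therefore describe the simulated runs and are not the sensitivity of each real comparison. Whether they differ between comparisons by more than random draws was not tested. None of 20 unchanged simulated lists was called in any comparison (0 of 20). The simulated noise was drawn independently for each gene, so these runs do not show how correlation between list members affects the list tests.

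The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean FPKM of at least 5, scaling to TPM, median-ratio scaling, quantile normalization, limma without a trend or with robust variances, only the 6 libraries compared, the replicate number as a block, each library left out in turn, and a log2 change of at least 1. After seeing the data, 2 more were added: leaving out experimental replicate 2 with intervention replicate 1, and removing the trend of each library on GC content and length. A change of sign between 2 values that both missed the threshold was counted as no change. One in which only the alternative passed the threshold was counted as stronger. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.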

Results

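HT22 cells were profiled by mRNA sequencing in 9 libraries, 3 each from the experimental, intervention and control groups. Summed FPKM was 316912 to 339943 per library. At least 1 FPKM was reached by 11646 to 11732 genes in the control libraries, 11154 to 11267 in the experimental libraries and 11308 to 11394 in the intervention libraries. Mitochondrial genes held 16.5% to 18.3% of the summed FPKM, and mt-Co1 was the most abundant gene in all 9 libraries. Across genes, which are not independent replicates, the correlation between libraries of 1 group was 0.990 to 0.994. It was 0.983 to 0.992 between experimental and intervention libraries, 0.936 to 0.951 between control and intervention libraries, and 0.916 to 0.931 between control and experimental libraries.

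**Figure D1:**
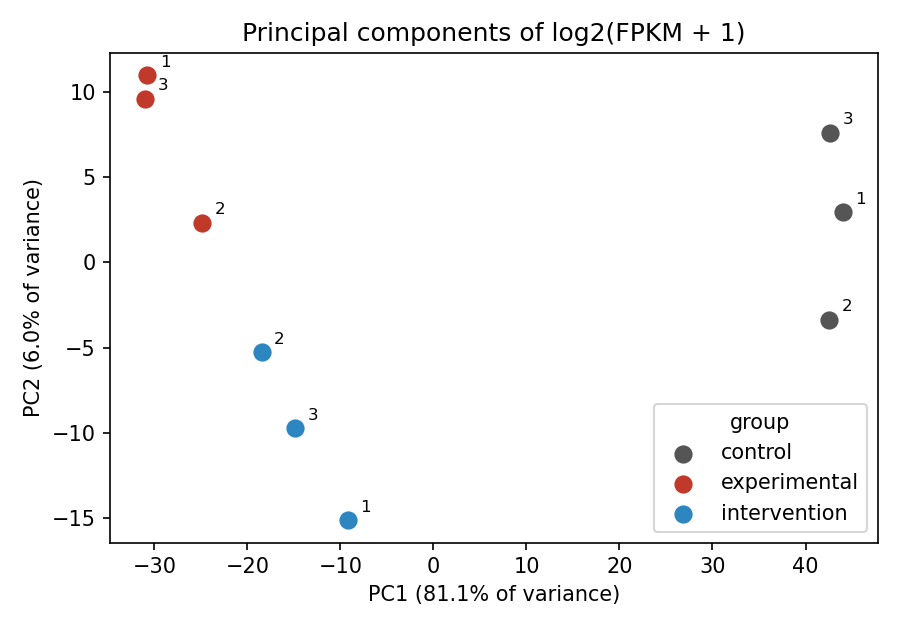
Principal components of log2(FPKM + 1) for the 9 libraries, 1 point per library, coloured by group and numbered by replicate. The first component (horizontal, 81.1% of variance) places the control libraries at 42.5 to 44.0, the intervention libraries at -18.5 to -9.23 and the experimental libraries at -31.0 to -24.9.

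The first comparison set the experimental group against the control group. Experimental cells held far more mRNA for Hmox1, the enzyme that breaks down heme, at 2211 ± 220 FPKM against 21.7 ± 2.94 in controls (SD, n = 3 each), a ratio of 102. NRF2 antioxidant targets, heat shock chaperones and genes of the integrated stress response rose, whereas genes of cholesterol synthesis, glycolysis, extracellular matrix and mitosis fell. As lists, only the NRF2 targets and the integrated stress response kept their call with an estimated correlation, while heat shock (adjusted p = 0.173), cholesterol synthesis (0.281), hypoxia and glycolysis (0.516), matrix (0.173) and mitosis (0.507) lost it. Slc7a11, the cystine importer subunit that feeds glutathione synthesis, was 1 of 4 NRF2 targets that fell, from 22.5 ± 3.22 to 1.70 ± 0.0458 FPKM. Of 11974 genes tested, 2809 were higher and 6047 lower, and 1319 of the 8856 called genes differed by at least 1 log2 unit (363 higher, 956 lower).

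That split of directions depends on the scaling of the FPKM. The median difference of all genes was -0.21 log2 units as deposited and 0.003 after median-ratio scaling, when 4380 genes were higher and 4357 lower. Quantile normalization gave 4172 higher and 4432 lower. Both of these scalings centre the genes, so a nearly even split is partly built in, and scaling to TPM gave 2495 higher and 6444 lower. The same median was 0.095 before and 0.001 after median-ratio scaling for intervention against experimental, and -0.104 and 0.009 for intervention against control. Changes of gene lists are therefore also given relative to the median of all genes.

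Hmox1 (chromosome 8, 75093621 to 75100589, plus strand of mm10) had the largest difference of the named genes, 6.61 log2 units (SE 0.12, adjusted p = 4.35e-10). Iron storage genes rose with it: Fth1, the ferritin heavy chain, went from 418 ± 29.6 to 1303 ± 16.4 FPKM (adjusted p = 2.22e-08) and Ftl1, the light chain, from 824 ± 21.3 to 2356 ± 14.4 (adjusted p = 1.23e-08). The heme exporter Flvcr1 rose 3.30-fold (adjusted p = 3.68e-08). Tfrc, the transferrin receptor that imports iron, fell from 57.5 ± 1.72 to 20.4 ± 3.50 FPKM (adjusted p = 2.3e-06). Of 27 measured genes of heme and iron handling, 11 rose and 12 fell (11 and 13 adjusted over the list alone), 14 rose and 9 fell after median-ratio scaling, and camera did not call the list (adjusted p = 0.127). Fry, which tests a list against no change, called it upward (adjusted p = 1.05e-06).

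Of 31 measured NRF2 targets, 25 rose and 4 fell, with the same counts adjusted over the list alone. The list's median stood 1.74 log2 units above that of all genes (camera adjusted p = 3.16e-13, adjusted p = 0.0117 with an estimated correlation). Gclm, the regulatory subunit of the enzyme that starts glutathione synthesis, rose from 5.01 ± 0.355 to 65.0 ± 1.08 FPKM. Srxn1, which repairs oxidised peroxiredoxins, rose from 24.5 ± 1.33 to 354 ± 15.2, Nqo1, a quinone reductase, from 15.9 ± 1.22 to 119 ± 3.90, and Txnrd1, thioredoxin reductase, from 26.9 ± 1.43 to 216 ± 13.1 (adjusted p at most 5.49e-09). Osgin1 rose 18.6-fold and Pgd, of the pentose phosphate pathway, 5.11-fold. Slc7a11 (chromosome 3, 49892526 to 50443614, minus strand of mm10) had a log2 difference of -3.11 (SE 0.09, adjusted p = 1.2e-08), and its 3 experimental values of 1.65 to 1.74 FPKM all lay below its 3 control values of 19.2 to 25.7.

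Integrated stress response genes rose in 26 of 28 measured cases and fell in 0 (26 and 1 adjusted over the list alone), with a median 1.04 log2 units above all genes (camera adjusted p = 5.76e-15, adjusted p = 0.0173 with an estimated correlation). Ddit3, the stress factor CHOP, rose 3.96-fold, Slc3a2, the heavy chain that partners Slc7a11, 8.77-fold, and Chac1, a glutathione-degrading enzyme, 1.76-fold. Atf3 was too low to test, at 0.127 FPKM in experimental, 0.030 in intervention and 0.0167 in control libraries on average. Unfolded protein response genes rose in 20 of 22 cases, led by Hspa5, the chaperone BiP, from 101 ± 3.10 to 546 ± 27.3 FPKM (list adjusted p = 5.07e-10, adjusted p = 0.0828 with an estimated correlation). Heat shock genes rose in 18 of 19 cases (adjusted p = 3.54e-13, adjusted p = 0.173 with an estimated correlation). Among these, Hspa1a went from 8.21 ± 0.55 to 304 ± 74.8 FPKM, Hspa1b from 23.8 ± 1.57 to 868 ± 230, and Hsph1 rose 8.62-fold. Proteasome subunits rose in 26 of 28 cases, with Psmc2 at 2.33-fold (adjusted p = 3.54e-13, adjusted p = 0.208 with an estimated correlation). Ribosomal protein genes rose in 30 of 33 cases, by a median of 0.39 log2 units (adjusted p = 1.77e-10, adjusted p = 0.281 with an estimated correlation), and in 20 cases with 4 lower after quantile normalization. For these 4 lists the counts adjusted over the list alone were the same.

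Among immediate early genes, which respond first to growth and stress signals, 14 of 24 rose and 7 fell (adjusted p = 0.000407, adjusted p = 0.299 with an estimated correlation). Fosl1, an AP-1 subunit, rose 14.3-fold and Ier3 11.8-fold, while Npas4, a neuronal activity gene, fell by 1.53 log2 units. Ptgs2, the inducible cyclooxygenase, rose from 5.71 ± 0.437 to 249 ± 47.6 FPKM (adjusted p = 3.68e-08). Ferroptosis regulators as a list were not called (4 of 21 higher, 14 lower, adjusted p = 0.537). The list holds both genes that restrain and genes that promote ferroptosis, so a missing list call in any comparison does not show that its genes were unchanged. Gpx4, which reduces lipid peroxides, fell from 90.1 ± 9.42 to 63.2 ± 4.33 FPKM (adjusted p = 5e-04). Acsl4, which loads membranes with polyunsaturated fatty acids, fell from 33.7 ± 1.79 to 26.9 ± 1.05 (adjusted p = 0.000312), a call lost after median-ratio scaling (adjusted p = 0.305). In the p53 and apoptosis list 11 of 28 rose and 11 fell (adjusted p = 0.0563), or 16 and 9 after median-ratio scaling. The growth-arrest gene Gadd45a rose 6.61-fold and Cdkn1a, which encodes the cell-cycle inhibitor p21, 2.37-fold. Metallothionein and metal genes rose in 5 of 7 cases and fell in 1, with Mt2 at 1.53-fold (adjusted p = 0.0167, adjusted p = 0.173 with an estimated correlation), a list call also lost with a mean FPKM of at least 5. All of these counts were the same adjusted over the list alone. After median-ratio scaling immediate early genes were 16 higher and 4 lower and ferroptosis regulators 7 and 12.

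All 24 measured cholesterol synthesis genes fell, by a median of 1.15 log2 units below that of all genes (adjusted p = 1.75e-08, adjusted p = 0.281 with an estimated correlation). Lss, lanosterol synthase, went from 39.5 ± 1.14 to 8.32 ± 0.50 FPKM and Hmgcs1 from 142 ± 4.24 to 36.5 ± 2.20. Fatty acid and lipid genes fell in 20 of 24 cases, with the desaturase Scd2 from 607 ± 11.8 to 267 ± 5.82 FPKM (adjusted p = 0.000788, adjusted p = 0.208 with an estimated correlation). Hypoxia and glycolysis genes fell in 21 of 26 cases and rose in 3 (adjusted p = 0.00269, adjusted p = 0.516 with an estimated correlation). Pfkl, the liver-type phosphofructokinase, went from 53.8 ± 9.03 to 6.11 ± 0.611 FPKM, Bnip3, a mitophagy receptor, fell 8.80-fold, and Ldha, lactate dehydrogenase, went from 369 ± 55.3 to 86.9 ± 4.42. Matrix and TGF-beta genes fell in 18 of 23 cases and rose in 3 (adjusted p = 0.00474, adjusted p = 0.173 with an estimated correlation), with the YAP target Ccn2 from 23.9 ± 1.78 to 1.77 ± 0.397 FPKM and the collagen Col3a1 from 174 ± 11.4 to 44.6 ± 1.79. Interferon-stimulated genes fell in 13 of 19 cases and rose in 2 (adjusted p = 0.0402, adjusted p = 0.299 with an estimated correlation), and that list call was also lost with a pseudocount of 0.1, a mean FPKM of at least 5, scaling to TPM and the GC and length trend removed. These counts were the same adjusted over the list alone. After median-ratio scaling fatty acid and lipid genes were 4 higher and 18 lower and interferon-stimulated genes 4 and 13.

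Mitosis genes fell in 28 of 30 cases (29 adjusted over the list alone), with cyclin A2, Ccna2, from 69.0 ± 5.42 to 35.3 ± 1.81 FPKM (adjusted p = 6.84e-05, adjusted p = 0.507 with an estimated correlation). DNA replication genes split into 5 higher and 13 lower of 30 and were not called as a list (adjusted p = 0.935), and the split turned to 16 higher and 6 lower after median-ratio scaling. Nuclear oxidative phosphorylation genes fell in 25 of 35 cases, with Sdha at 27.5 ± 1.98 against 55.5 ± 1.63 FPKM (adjusted p = 0.00794, adjusted p = 0.668 with an estimated correlation), and in 19 with 5 higher after median-ratio scaling. Of 13 mitochondrially encoded genes, mt-Co1 alone was called (1.13-fold, adjusted p = 0.0414, 0 called adjusted over the list alone), and that call was lost when any of several libraries was left out (for example adjusted p = 0.13 without experimental replicate 1). After median-ratio scaling all 13 were higher and camera called the list (adjusted p = 0.00986), and after quantile normalization 5 were lower. Autophagy and lysosome genes were 8 higher and 17 lower of 33 (adjusted p = 0.541), or 15 higher and 9 lower after median-ratio scaling, and the autophagy receptor Sqstm1 rose 8.06-fold. The NF-kB and cytokine list was 2 higher and 9 lower of 18 (adjusted p = 0.544), or 6 and 8 after median-ratio scaling, with the chemokine Ccl7 from 104 ± 9.15 to 27.8 ± 3.06 FPKM. All 30 neuronal genes had an entry, but only 8 passed the filter of at least 1 FPKM in at least 3 libraries. Of these 8, 1 was higher and 4 lower (adjusted p = 0.649). Except where given, the counts were the same adjusted over the list alone. Among markers of other cell types, Gja1 and Cd68 were higher and Slc1a3, Sox9, Tmem119, Pdgfra and Cspg4 lower. These markers lay between 0.93 and 26.5 FPKM on average in either group, and the Sox9 call was lost after median-ratio scaling (adjusted p = 0.15). Neat1, a nuclear noncoding RNA whose share can shift with RNA quality, fell from 16.4 ± 3.21 to 5.74 ± 0.894 FPKM. Malat1, of the same kind, fell from 143 ± 40.6 to 91.8 ± 12.9 (adjusted p = 0.0141). That call was lost, among others, after median-ratio scaling (adjusted p = 0.125), with no filter on low values (0.0526) and without experimental replicate 2 (0.0574).

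**Figure D2:**
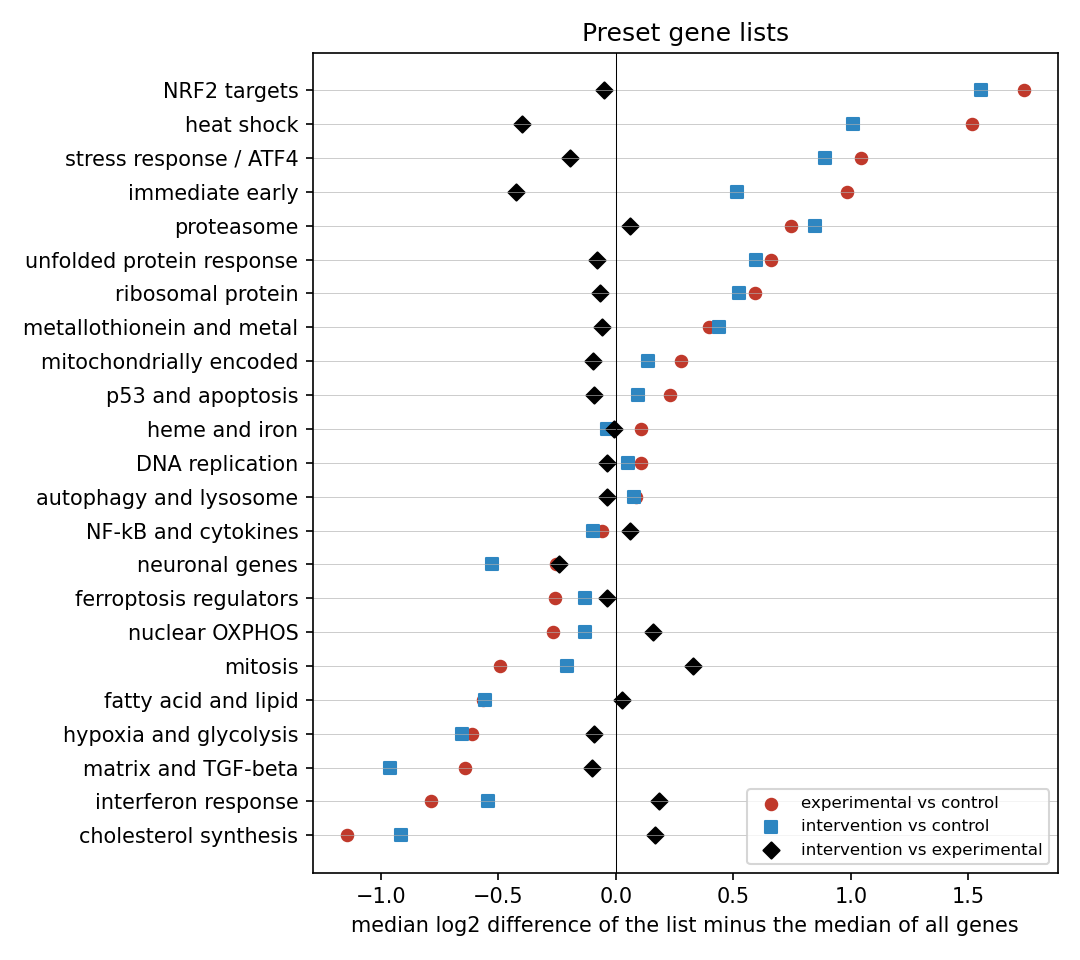
Median log2 difference of each of the 23 tested gene lists (rows), minus the median of all genes (horizontal axis, log2 units), for the 3 comparisons. NRF2 targets lie highest at 1.74 and cholesterol synthesis lowest at -1.15 in experimental against control, and immediate early and heat shock genes lie lowest in intervention against experimental at -0.42 and -0.40.

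The next comparison set the intervention group against the experimental group. Slc7a11 rose from 1.70 ± 0.0458 to 27.7 ± 2.02 FPKM (SD, n = 3 each), a ratio of 16.3. The inducible heat shock genes Hspa1a and Hspa1b fell 3.30-fold and 3.24-fold, and Ptgs2 fell 2.32-fold, from 249 ± 47.6 to 107 ± 31.9 FPKM. Of 30 mitosis genes 28 rose, or 19 after median-ratio scaling, with a list median 0.33 log2 units above that of all genes (adjusted p = 0.428 with an estimated correlation). Most other differences were small. Of 11974 genes, 1906 were higher and 431 lower, and 8 of these differed by at least 1 log2 unit (2 higher, 6 lower). Apart from Slc7a11, Hspa1a, Hspa1b and Ptgs2, those 8 were Ttr, which was higher, and the predicted genes Gm14794, Gm26448 and Gm45053, which were lower. These were named after their values were seen, and none of them reached a mean of 5 FPKM in either group.

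The number of called genes rests on single libraries. It was 1 without experimental replicate 1, 4 without experimental replicate 3, 6 without intervention replicate 1 and 939 without intervention replicate 3, while all 2337 differences kept their sign and 3355, 3375 and 3161 genes had an unadjusted p under 0.05 in the first 3 of these. Without a filter on low values 358 genes were called, with quantile normalization 1038 (451 higher, 587 lower), and with median-ratio scaling 1513, when the split turned to 567 higher and 946 lower.

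Slc7a11 had a log2 difference of 3.41 (SE 0.09, adjusted p = 8.37e-08), and was the 1 gene called in all 9 fits that left out a library, with adjusted p = 2.41e-06 without experimental replicate 1. The calls of the other genes named for this comparison were each lost in at least 1 of those fits. Other genes that rose were mt-Tt, a mitochondrial tRNA gene, from 29.2 ± 7.09 to 56.2 ± 4.36 FPKM, the linker histone gene H1f0 from 70.6 ± 12.5 to 122 ± 25.6, the water channel gene Aqp5 from 4.98 ± 0.546 to 9.58 ± 3.32, and the mitotic kinesin Kif2c from 15.2 ± 2.81 to 25.1 ± 3.44 (adjusted p at most 0.0198). Among the largest decreases, Hspa1a went from 304 ± 74.8 to 92.0 ± 36.8 FPKM and Hspa1b from 868 ± 230 to 268 ± 112 (adjusted p = 0.0151 for both). The co-chaperone gene Bag3 went from 91.2 ± 13.0 to 52.8 ± 9.31 and Ppp1r15a, which reverses eIF2alpha phosphorylation, from 74.8 ± 12.6 to 40.5 ± 9.10 (adjusted p at most 0.0153).

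Heat shock genes fell in 13 of 19 cases (14 adjusted over the list alone, camera adjusted p = 1.21e-15, adjusted p = 0.159 with an estimated correlation). Immediate early genes fell in 16 of 24 cases (17 adjusted over the list alone), with Ier3 from 249 ± 27.9 to 152 ± 22.1 FPKM (adjusted p = 5.22e-16, adjusted p = 0.148 with an estimated correlation). Integrated stress response genes fell in 11 of 28 cases (1 higher and 11 lower adjusted over the list alone, adjusted p = 3.47e-08, adjusted p = 0.148 with an estimated correlation), among them Sesn2 at 38.6 ± 3.82 against 24.5 ± 3.88 FPKM, Chac1 at 60.3 ± 3.05 against 51.7 ± 3.76 and Ddit3 at 98.2 ± 4.42 against 82.2 ± 5.41. In the unfolded protein response list 4 of 22 fell (1 higher and 4 lower adjusted over the list alone), with Hspa5 from 546 ± 27.3 to 441 ± 63.2 (adjusted p = 0.033, adjusted p = 0.499 with an estimated correlation). That list call was lost under 8 of 24 alternatives, among them leaving out experimental replicate 2, intervention replicate 1 or intervention replicate 3, no filter on low values, quantile normalization and fry.

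Mitosis genes rose in 28 of 30 cases, 30 adjusted over the list alone and 19 after median-ratio scaling (adjusted p = 1.98e-11, adjusted p = 0.428 with an estimated correlation). Hmmr, a spindle-associated protein gene, went from 11.9 ± 0.929 to 17.9 ± 1.61 FPKM and the spindle motor Kif11 from 14.9 ± 1.60 to 20.4 ± 0.93. Nuclear oxidative phosphorylation genes rose in 16 of 35 cases, 28 adjusted over the list alone and 3 after median-ratio scaling, with the complex I subunit Ndufa9 from 16.6 ± 0.84 to 22.5 ± 1.75 (adjusted p = 1.72e-05, adjusted p = 0.524 with an estimated correlation). Cholesterol synthesis genes rose in 13 of 24 cases, 18 adjusted over the list alone and 5 after median-ratio scaling, with Hmgcs1 from 36.5 ± 2.20 to 50.8 ± 6.41 (adjusted p = 0.000106, adjusted p = 0.499 with an estimated correlation). Interferon-stimulated genes rose in 8 of 19 cases, 10 adjusted over the list alone and 4 after median-ratio scaling (adjusted p = 0.0143, adjusted p = 0.428 with an estimated correlation), a list call also lost with a mean FPKM of at least 5 and with the GC and length trend removed. Proteasome genes rose in 6 of 28 cases, 13 adjusted over the list alone and 2 after median-ratio scaling (adjusted p = 0.000999, adjusted p = 0.532 with an estimated correlation), and the list call was lost after that scaling (adjusted p = 0.0664).

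Hmox1 fell from 2211 ± 220 to 1469 ± 204 FPKM (adjusted p = 0.017) and Tfrc from 20.4 ± 3.50 to 13.8 ± 1.96 (adjusted p = 0.0212). Fth1 stood at 1303 ± 16.4 in experimental and 1250 ± 19.0 FPKM in intervention libraries (adjusted p = 0.448) and Ftl1 at 2356 ± 14.4 and 2463 ± 43.6 (adjusted p = 0.328). Among heme and iron genes 2 of 27 rose and 4 fell, with the same counts adjusted over the list alone, and 0 and 6 after median-ratio scaling (adjusted p = 0.318). NRF2 targets were 8 higher and 7 lower of 31, 10 and 9 adjusted over the list alone, and 2 higher and 9 lower after median-ratio scaling (adjusted p = 0.219). Txnrd1 fell 1.34-fold and Srxn1 1.22-fold, Nqo1 rose 1.15-fold (adjusted p = 0.0464, lost after median-ratio scaling), and Gclm stood at 65.0 ± 1.08 and 58.4 ± 2.12 (adjusted p = 0.068). Gpx4 stood at 63.2 ± 4.33 and 76.2 ± 7.05 FPKM (adjusted p = 0.0621) and Acsl4 at 26.9 ± 1.05 and 24.7 ± 0.561 (adjusted p = 0.141). Ferroptosis regulators were 3 higher and 3 lower of 21, 7 and 4 adjusted over the list alone, and 2 higher and 7 lower after median-ratio scaling (adjusted p = 0.398).

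The remaining lists follow. The p53 and apoptosis list had 6 higher and 5 lower of 28, 7 and 6 adjusted over the list alone, or 2 higher and 7 lower after median-ratio scaling. Camera placed that list below all genes (adjusted p = 0.0469, adjusted p = 0.43 with an estimated correlation), although its median was 0.003 and its mean 0.015, both above 0, and the call was lost under 11 of 24 alternatives, among them median-ratio scaling (adjusted p = 0.0842) and leaving out experimental replicate 2, intervention replicate 1 or control replicate 2. Matrix and TGF-beta genes were 2 higher and 5 lower of 23, with the same counts adjusted over the list alone, and 1 and 8 after median-ratio scaling (adjusted p = 0.00168, adjusted p = 0.159 with an estimated correlation), a list call also lost with no filter on low values and with fry. In the hypoxia and glycolysis list 4 of 26 fell, 2 adjusted over the list alone (adjusted p = 0.0308, adjusted p = 0.65 with an estimated correlation). That list call was lost under 7 of 24 alternatives, among them leaving out experimental replicate 2 or intervention replicate 2, no filter on low values, quantile normalization and fry. None of the 8 neuronal genes was called (0 of 8, also adjusted over the list alone), while the list lay 0.24 log2 units below all genes (adjusted p = 0.000999, adjusted p = 0.159 with an estimated correlation), a call also lost with fry. Fatty acid and lipid genes were 6 higher and 1 lower of 24, 11 and 2 adjusted over the list alone, and 1 higher and 3 lower after median-ratio scaling (adjusted p = 0.37). DNA replication genes were 4 higher and 1 lower of 30, 6 and 2 adjusted over the list alone, and 0 higher and 7 lower after median-ratio scaling (adjusted p = 0.37). NF-kB and cytokine genes were 6 higher and 2 lower of 18, the same adjusted over the list alone, and 3 and 2 after median-ratio scaling (adjusted p = 0.746), and autophagy and lysosome genes 5 higher and 1 lower of 33, 6 and 1 adjusted over the list alone, or 0 higher and 1 lower after median-ratio scaling (adjusted p = 0.746). Metallothionein and metal, ribosomal protein and mitochondrially encoded lists were not called (adjusted p = 0.37, 0.221 and 0.0614). After median-ratio scaling camera called the ribosomal protein list (adjusted p = 0.00429) and the mitochondrially encoded list (adjusted p = 0.0104) as lower. With the FPKM as deposited limma called 0 of their 7, 33 and 13 genes. Adjusted over the list alone, 1 metal gene was higher and 1 lower and 0 genes of the other lists were called. Of the markers of other cell types, Tmem119 rose from 0.93 ± 0.171 to 1.63 ± 0.331 FPKM and Pdgfra from 6.01 ± 0.437 to 7.28 ± 0.444. Malat1 (adjusted p = 0.433) and Neat1 (adjusted p = 0.722) were not called.

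**Figure D3:**
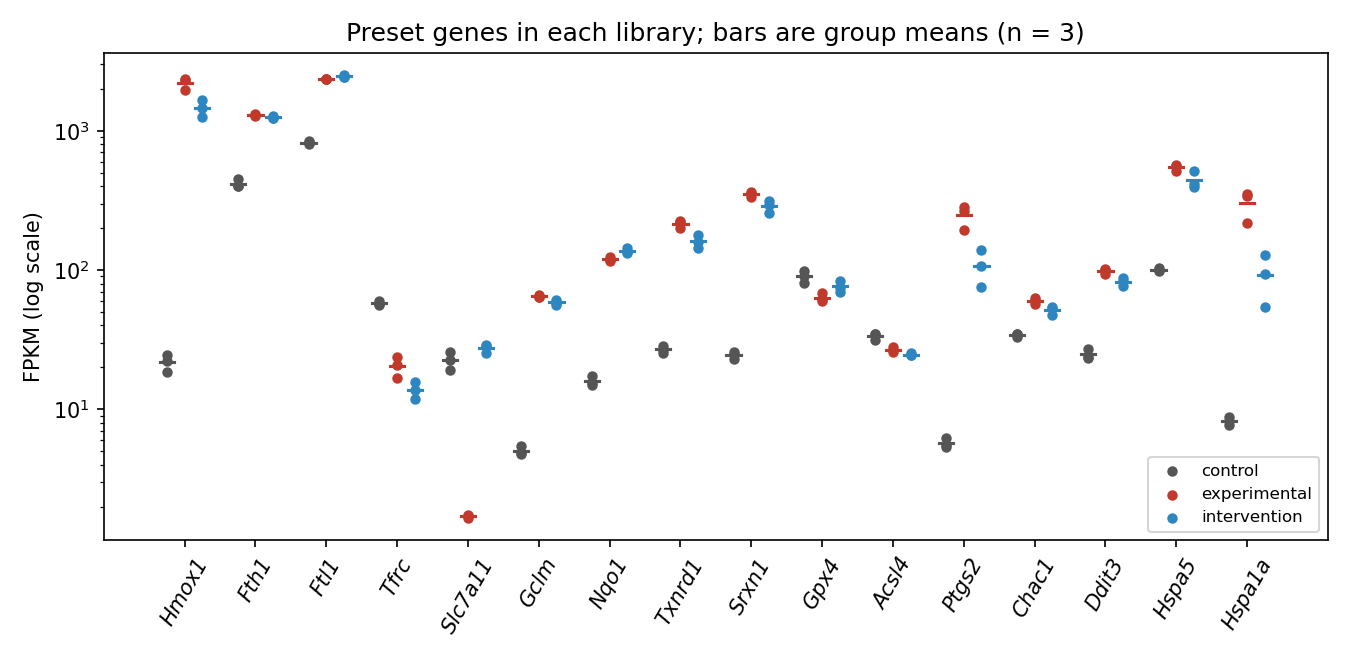
FPKM (vertical, log scale) of 16 genes named in advance in each of the 9 libraries, as points coloured by group, with bars at the group means (n = 3). Slc7a11 stands at 22.5 in control, 1.70 in experimental and 27.7 in intervention libraries on average, whereas Hmox1 stands at 21.7, 2211 and 1469.

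The last pairwise comparison set the intervention group against the control group. Intervention cells still differed widely from control cells, with Hmox1 at 1469 ± 204 against 21.7 ± 2.94 FPKM (SD, n = 3 each), a ratio of 67.6. NRF2 targets, stress response and heat shock genes were higher and cholesterol synthesis, glycolysis and matrix genes lower. As lists, heat shock (adjusted p = 0.167 with an estimated correlation), cholesterol synthesis (0.261), hypoxia and glycolysis (0.365) and matrix (0.0626) lost their call with an estimated correlation, as they did in experimental against control. Slc7a11 stood at 27.7 ± 2.02 against 22.5 ± 3.22 FPKM. Of 11974 genes, 2890 were higher and 4926 lower, or 3912 and 3876 after median-ratio scaling. At least 1 log2 unit separated 665 of the 7816 called genes (237 higher, 428 lower).

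Ptgs2 was 18.8-fold higher, Srxn1 11.8-fold, Gclm 11.7-fold, Hspa1b 11.3-fold and Hspa1a 11.2-fold higher than in controls. Gsta4, a glutathione transferase that clears lipid aldehydes, went from 27.5 ± 2.84 to 266 ± 20.5 FPKM and Nqo1 from 15.9 ± 1.22 to 137 ± 6.70 (adjusted p at most 5.39e-09). Fth1 was 2.99-fold higher and Ftl1 2.99-fold, while Tfrc fell from 57.5 ± 1.72 to 13.8 ± 1.96 FPKM (adjusted p = 6.35e-07). Ccn2 fell from 23.9 ± 1.78 to 2.04 ± 0.429, Pdk1, a kinase that holds back pyruvate oxidation, from 13.7 ± 2.09 to 1.32 ± 0.167 and the matrix protease gene Adamts5 from 13.2 ± 0.748 to 2.03 ± 0.271. The log2 difference of Slc7a11 was 0.30 (SE 0.09, adjusted p = 0.0174). That call held under 16 of 22 alternatives, whose adjusted p ran from 0.00214 to 0.102, and was lost, among others, without intervention replicate 1 (0.0524), intervention replicate 3 (0.0617) or control replicate 1 (0.0606). Gpx4 stood at 76.2 ± 7.05 against 90.1 ± 9.42 FPKM (adjusted p = 0.0383), a call that was lost, among others, after median-ratio scaling (adjusted p = 0.264) and without experimental replicate 3 (0.0511), intervention replicate 2 (0.132), intervention replicate 3 (0.094), control replicate 1 (0.0906) or control replicate 2 (0.134).

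NRF2 targets were higher in 27 of 31 cases and lower in 2 (adjusted p = 5.72e-16, adjusted p = 0.00659 with an estimated correlation), and integrated stress response genes higher in 25 of 28 and lower in 1 (adjusted p = 4.24e-14, adjusted p = 0.022 with an estimated correlation). All 28 proteasome genes were higher, with Psmc2 from 17.9 ± 0.0404 to 43.9 ± 0.936 FPKM (adjusted p = 5.72e-16, adjusted p = 0.167 with an estimated correlation). All 19 heat shock genes (adjusted p = 2.06e-11, adjusted p = 0.167 with an estimated correlation), 21 of 22 unfolded protein response genes (adjusted p = 8.32e-11, adjusted p = 0.0626 with an estimated correlation) and 30 of 33 ribosomal protein genes (adjusted p = 1.12e-10, adjusted p = 0.303 with an estimated correlation) were higher. Metallothionein and metal genes were higher in 5 of 7 cases and lower in 1, or 2 adjusted over the list alone (adjusted p = 0.0384, adjusted p = 0.167 with an estimated correlation), a list call also lost after median-ratio scaling (adjusted p = 0.0518), after quantile normalization and with a mean FPKM of at least 5.

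All 24 cholesterol synthesis genes were lower (adjusted p = 2.7e-10, adjusted p = 0.261 with an estimated correlation). Hypoxia and glycolysis genes were lower in 23 of 26 cases and higher in 1 (adjusted p = 1.3e-05, adjusted p = 0.365 with an estimated correlation), matrix and TGF-beta genes lower in 18 of 23 and higher in 2 (adjusted p = 4.65e-05, adjusted p = 0.0626 with an estimated correlation). Fatty acid and lipid genes were lower in 20 of 24 and higher in 1, or 2 adjusted over the list alone (adjusted p = 6.43e-05, adjusted p = 0.167 with an estimated correlation). Mitosis genes were lower in 18 of 30 cases and higher in 1 (adjusted p = 0.0429, adjusted p = 0.743 with an estimated correlation), a list call that ended with median-ratio scaling (adjusted p = 0.071) and when intervention replicate 2, intervention replicate 3, control replicate 2 or control replicate 3 was left out. Lists not called were heme and iron (12 higher, 11 lower of 27, adjusted p = 0.189), ferroptosis regulators (6 and 12 of 21, 0.679), p53 and apoptosis (13 and 11 of 28, 0.132), NF-kB and cytokines (4 and 9 of 18, or 5 and 6 after median-ratio scaling, 0.553) and interferon response (3 and 13 of 19, 0.0523, called after median-ratio scaling at 0.0244). Immediate early genes (13 and 8 of 24, 0.0758), autophagy and lysosome (9 and 12 of 33, or 16 and 8 after median-ratio scaling, 0.397), nuclear oxidative phosphorylation (3 and 20 of 35, or 6 and 12 after median-ratio scaling, 0.132), DNA replication (4 and 12 of 30, or 9 and 6 after median-ratio scaling, 0.701), neuronal genes (1 and 6 of 8, 0.185) and mitochondrially encoded genes (1 and 0 of 13, or 6 and 0 after median-ratio scaling and 0 and 3 after quantile normalization, 0.247) were not called either. Adjusted over the list alone, oxidative phosphorylation had 4 higher and 22 lower and the mitochondrially encoded list 0 called, and the other lists described for this comparison without such a count were the same. Markers of other cell types kept the directions seen in experimental against control, with Gja1 at 7.65 ± 0.09 against 3.53 ± 0.355 FPKM and Tmem119 at 1.63 ± 0.331 against 10.3 ± 0.805. Neat1 (adjusted p = 1.76e-05) and Malat1 (adjusted p = 0.00329) were lower.

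The design also allows the question whether the intervention group differed from the experimental group in the direction of the control group. Of the genes called both in experimental against control and in intervention against experimental, 2107 differed in opposite directions, such as Slc7a11, Hspa1a and Ptgs2, and 66 in the same direction, such as Tfrc. Of the 2107, 1724 were lower and then higher and 383 higher and then lower, or 503 and 867 after median-ratio scaling. Independent lists would share 1064 genes in opposite directions, and simulated unchanged groups that share the experimental libraries gave a mean of 0.02 and at most 1. Unchanged groups have almost no called genes, so that simulated count is near 0 by design and says nothing about the shared libraries. Across genes, the correlation of the 2 sets of differences was -0.641 against a simulated -0.499, and their covariance -0.081 against a simulated -0.00556, a difference of -0.0754. The simulated values hold the shared libraries and the independent lists do not, so part of the overlap beyond 1064 may come from the shared experimental libraries, of which 3 are too few to split. The count of 2107 fell to 1, 3, 5 and 859 without experimental replicate 1, experimental replicate 3, intervention replicate 1 and intervention replicate 3. Of the 8856 genes called in experimental against control, 7235 (81.7%) were called with the same sign in intervention against control and 6 with the opposite sign. These comparisons share the 3 control libraries, so part of this may come from them. Independent lists would share 3166 genes with the same sign, and simulated unchanged groups shared a mean of 0, again with almost no called genes.

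**Figure D4:**
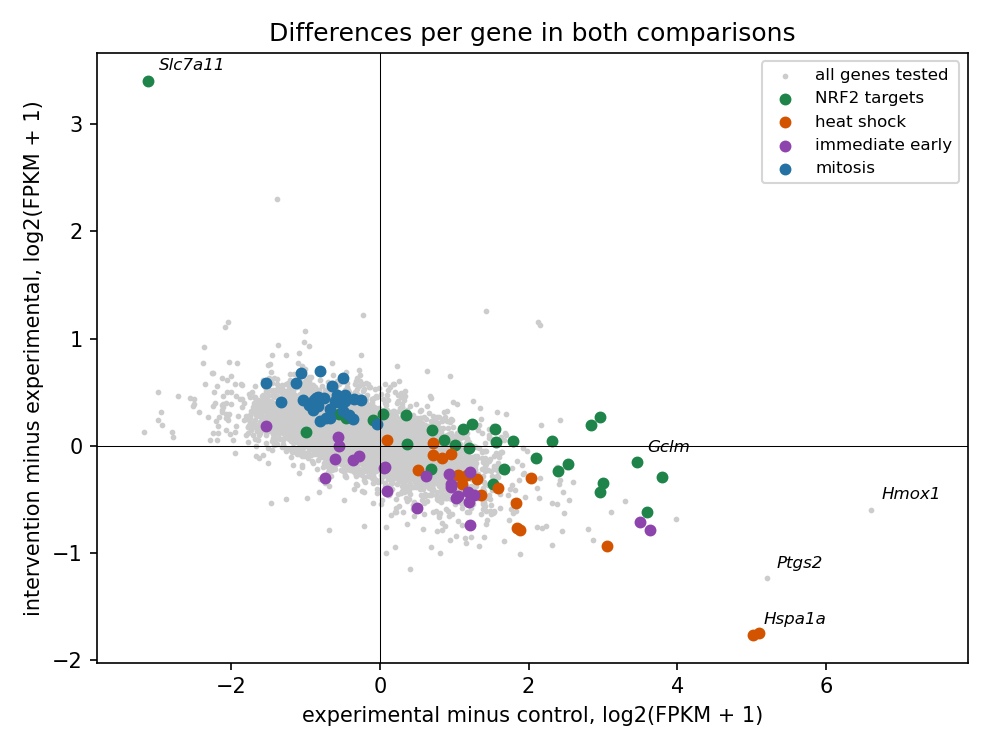
Difference per gene between experimental and control (horizontal) and between intervention and experimental (vertical), both in log2(FPKM + 1), 1 point per tested gene, with 4 gene lists coloured. Slc7a11 lies apart at -3.11 and 3.41, heat shock genes such as Hspa1a (5.02 and -1.76) lie at the lower right, and Gclm (3.46 and -0.15) lies near the horizontal line at 0.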

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

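Among the alternatives, the pair of libraries left out together and the removed GC and length trend were chosen after seeing the data. The counts of genes in experimental against control and in intervention against control stayed within 1.5 times except with a mean FPKM of at least 5 (5702 and 5129, from 7361 genes tested) and with a log2 change of at least 1 (1319 and 665, against 8 for intervention against experimental), where fewer genes can pass. Leaving out 1 library gave 8314 to 8841 and 7169 to 7785 genes. In the same fits intervention against experimental ranged from 1 to 2571 genes and the opposite-direction count from 1 to 2315. With the GC and length trend removed those counts were higher, at 3051 and 2691. Those counts were 358 and 323 with no filter on low values, 1513 and 1370 with median-ratio scaling, 1038 and 937 with quantile normalization, and 984 and 916 without experimental replicate 2 and intervention replicate 1, and the cause was not tested. With the replicate number as a block they were 1268 and 1168. The numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.182 to 0.11, 2 of 9 pairs over 0.1, and 0 libraries correlated best with their own number in both other groups. In intervention against experimental, 89 of the 90 called among the named genes lost their call under at least 1 alternative, against 6 of 109 in experimental against control and 3 of 113 in intervention against control, and none reversed (0 in each). Of list results, 78 became weaker, 36 of them with an estimated correlation, and 59 became stronger, 22 of them with fry. Among lists called by camera 1 had the other direction. With fry the p53 and apoptosis list had a median of 0.003 (adjusted p = 0.743) in intervention against experimental, upward where camera gave downward. Lists that camera did not call could not count as reversed. In that comparison fry called heme and iron (adjusted p = 0.0261), NRF2 targets and ferroptosis regulators (0.0106 each) upward, where camera gave downward. They count as stronger. Fry tests a list against no change and camera against the other genes, so these results answer different questions. Where camera made no call in experimental against control, fry called heme and iron and p53 and apoptosis upward. It called ferroptosis regulators, NF-kB and cytokines, DNA replication and neuronal genes downward (adjusted p at most 0.00271 for each). In intervention against control it called all lists that camera did not, except the mitochondrially encoded one (adjusted p at most 0.0406). The read depth is unknown, so it cannot be said which low genes lacked reads.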

Other observations

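In this part, the gene groups of this paragraph and of the next were chosen after the results were seen. So were the tests on Slc7a11, on shared libraries and on common scaling, and the splits that keep the control libraries together. The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, were higher in experimental than in control cells for 14 of 20 genes and lower for 4 (camera adjusted p = 1.16e-06 over these lists, adjusted p = 0.0203 with an estimated correlation). Nars rose from 58.2 ± 1.88 to 157 ± 6.95 FPKM and Gars from 94.3 ± 3.74 to 164 ± 3.81 (SD, n = 3 each), whereas Dars fell from 22.8 ± 1.65 to 13.9 ± 0.218 and Mars1 from 37.5 ± 0.903 to 23.1 ± 1.07. All 8 subunits of the chaperonin TRiC, which folds actin and tubulin, rose (adjusted p = 1.14e-05, adjusted p = 0.14 with an estimated correlation), or 7 after quantile normalization. Pentose phosphate genes were 5 higher and 1 lower of 8 (adjusted p = 0.00747, adjusted p = 0.0857 with an estimated correlation), with G6pdx, the entry enzyme, from 40.8 ± 0.654 to 98.0 ± 7.21 FPKM. The risen G6pdx, Pgd, Taldo1 and Tkt are also in the NRF2 list, and the synthetases Cars, Sars and Wars in the integrated stress response list. These results therefore partly repeat those of the preset lists.

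Caveolae genes, which shape small pits of the cell membrane, were 7 lower and 1 higher of 9 in experimental against control, though the list was not called (adjusted p = 0.0635, and 0.345 with an estimated correlation). Cav1 fell from 169 ± 7.53 to 33.5 ± 3.17 FPKM, Ehd2 from 36.8 ± 1.81 to 7.66 ± 0.71 and Cavin1 from 128 ± 4.78 to 45.2 ± 1.29, while Ehd1 rose from 41.0 ± 0.813 to 70.2 ± 0.575. Mitochondrial ribosome genes were 6 higher and 21 lower of 35 (adjusted p = 0.418), or 11 higher and 13 lower after median-ratio scaling. In intervention against experimental 15 of them rose and 0 fell, or 5 and 0 after median-ratio scaling (adjusted p = 0.000353, adjusted p = 0.611 with an estimated correlation). In that comparison limma called 2 synthetases higher and 2 lower, 0 TRiC subunits, 2 pentose phosphate genes higher and 4 caveolae genes higher. After median-ratio scaling these were 1 synthetase higher and 4 lower, 2 TRiC subunits lower, 1 pentose phosphate gene higher, and 1 caveolae gene higher and 1 lower.

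In experimental cells Slc7a11 fell by 3.11 log2 units, while the other 58 measured NRF2 and ATF4 targets had a median difference of 1.07 with 51 higher and 3 lower, which argues against a loss of that response as a whole. Genes overlapping the Slc7a11 locus gained 0.177% of the FPKM it lost, but 4 of these 5 genes have no value in the table, so an assignment of fragments to them stays open. In the intervention group Slc7a11 lay 2.73 log2 units above the line through all genes, against 1.98 for the next gene, Gm20521, which was not called (adjusted p = 0.0977), and the largest increase of another member of these lists was 0.30 log2 units, for Ephx1. Regulation of this gene alone and a measurement effect on this gene alone, such as reads of 1 exon or isoform, cannot be told apart with 1 value per gene. Coverage along the gene would be needed to tell them apart.

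Intervention libraries differed from experimental libraries toward the controls. The covariance was -0.081, while 100 simulations of unchanged groups went no lower than -0.00657, so noise independent between genes does not account for it. Those simulations held no spread common to many genes and no difference between experimental and control. The part of such a spread in the shared experimental libraries therefore stays open. The share of the experimental difference kept in intervention cells was 89.3% for NRF2 targets and 70.9% for heat shock genes. These were 18.4 points apart (95% bootstrap interval 8.7 to 27.1 from 10000 resamples of 3 libraries per group, or 17.8 points after median-ratio scaling). The 2 lists were set against each other after their differences had been seen, and 3 libraries give few distinct resamples. The interval may therefore be too narrow, and it does not exclude one common scaling of the response. For mitosis genes the share was 43.3% (25.8 to 60.3) and for proteasome genes 125.3% (115.7 to 135.5). Experimental replicate 2 and intervention replicate 1 lie at the edges of their groups, and without both 916 genes changed in opposite directions, which is under the 1053.5 set before the result as the sign that these libraries cause the pattern. A comparison added after that result found 1 to 2527 genes for the 8 other pairs, 6 of them also under 1053.5. Without experimental replicate 2 alone the count was 2315, and without intervention replicate 1 alone it was 5. The count therefore depended on which libraries were left out, and not only on their number. It did not rest on experimental replicate 2, while 6 other pairs lowered it as well, so the part of this pair as a whole stays open. A biological effect of what the intervention group received stays open too.

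More genes were lower than higher in experimental against control (68.3% of called genes), and after median-ratio scaling 49.9% were lower, under the 55% set before the result as the sign that the scaling of the deposited FPKM is the cause. That scaling centres the genes, which brings a nearly even split by itself, and scaling to TPM left 72.1% lower, so the part of the scaling stays open. After the trend on GC content and length was removed 68.8% were lower, but the median shift of each library was put back in that correction, so the share stays near its first value by design and the part of GC content and length stays open. The median difference of all genes was -0.195 after rescaling without the 20 genes of largest gain, whose summed gain was 5.66% of the experimental FPKM. It was -0.207 as deposited and -0.297 scaled to TPM, where the library totals are made equal. On this scale the 20 genes did not account for the whole shift, and how large a part they had stays open. FPKM divides out gene length, so these sums are not shares of fragments. No biological explanation of the excess was tested.

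Other splits of the libraries called fewer genes than the real groups. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes in each comparison: 8856 against at most 1 for experimental against control, 2337 against at most 5 for intervention against experimental, and 7816 against at most 0 for intervention against control. For genes changed in opposite directions, 1 of 100 assignments of the 9 libraries, the real one, gave 2107 and the highest other gave 187. Most of those assignments mix control libraries into the other groups, which by itself leaves few called genes, and the splits that keep the control libraries together are 10, too few for a share under 0.05, with at most 5 genes in the others.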
